A study of Escherichia coli with 9 samples.

How the data were processed

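The libraries were chromatin immunoprecipitations of a FLAG-tagged dCas9, a Cas9 without nuclease activity that binds DNA where a guide RNA directs it. Escherichia coli MG1655, a laboratory K-12 strain, carried dCas9 on plasmid pLC133 and a guide on plasmid psgRNAcos. Per the labels' protocols, cells grew in LB at 30 °C with 50 µg/ml kanamycin and 25 µg/ml chloramphenicol. dCas9 was induced with 1 nM anhydrotetracycline (aTc) at OD600 0.2, and cells were fixed with 1% formaldehyde at OD600 1.0. There were 9 libraries, 3 for each of 3 guides, grouped by the guide named in their titles: a control guide against lacZ, and guides with the AGGAA or ACCCA seed, both described as toxic. The seed is the stretch of the guide next to the PAM, the short motif Cas9 needs beside its site. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

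The submitters' processing notes name Bowtie2 2.3.4, SAMtools 1.9 and MACS3 3.0.0b1. Each deposited list holds the authors' summits for 1 library, with a 1-base position and a score, read as −log10 of a p-value or q-value in the form MACS writes; which of these, the read depth and any control library are not given in the sources used here. Scores were used within a list, to rank or filter summits and, for repeated genes, to compare the scores of copies. Between lists, only median scores were set side by side. Each list was a single library's, so replicates were compared by presence and position. Without read counts, the depth behind each summit is unknown, and a summit missing from a list is not evidence that dCas9 was absent there.

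The lists name the MG1655 chromosome without a sequence version. The gene table of assembly ASM584v2 (4651 genes) was used with them after 2 checks of the coordinates. Summits of the lacZ guide in 7 of 7 rrs genes of equal length, with starts from 223771 to 4208147, lay 135 to 138 bp from the nearer gene end. ACCCA summits in 12 of 12 insH genes, with starts from 274101 to 3652182, lay 137 to 138 bp from it. Neither a genome sequence nor gene strand was used here. Tests of seed and PAM sequences, and of regions upstream of start codons, were therefore not run, and neither was the part of the naming rule that asked for the guide's own seed and PAM at a region. In their place, each region was described as inside or outside annotated genes, and the 250 bp outside genes at either gene end served as flanks, on both sides because strand was not used.

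A region was a cluster of chromosomal summits from all 9 libraries with neighbours at most 50 bp apart. Its position was the median summit, not the highest one as planned; regions spanned a median of 1 bp and at most 113 bp. A region was guide-specific when present in 3 of 3 libraries of a guide and in 0 of 6 others. Libraries were compared by the Jaccard index, the regions shared by a pair over all regions of the pair. Group differences were tested by exact permutation over all 280 distinct assignments of 9 libraries to 3 groups of 3. Positions were tested by permutation, rotating a set of regions around the chromosome by 10000 random offsets, two-sided, or 1000 offsets, one-sided, for the overlap of guides. In that overlap, regions were built within each guide and paired when at most 50 bp apart. The 14 gene lists were tested by Fisher's exact test, two-sided, against all other genes, with Benjamini-Hochberg adjustment over 42 tests. For AGGAA and ACCCA the plan had been to compare with genes that hold a seed and PAM site but no such region. That background needs the sequence, so which genes could be hit was not controlled. Of 294 genes in the essential list, 290 matched a symbol in the table.

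The gene lists, the region definition, the naming rule and the tests of summit number, concordance, guide-specific regions and presence in lacZ were fixed before the data were examined. The naming rule took the 15 guide-specific regions with the best mean rank for AGGAA and ACCCA, 15 more in or beside essential genes, the best 10 for lacZ and the best 10 found in all 9 libraries. Added after seeing the data were the shares outside genes, the rotation test of gene lists, the permutation test of ranks in lacZ, the overlap of guides, repeated gene families, the comparison around the replication origin and stretches without summits. Alternatives were 25 or 100 bp between neighbouring summits, a score of at least 10, the best 500 or 1000 summits, 2 of 3 own libraries, and leaving out each library.

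Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The code was tested on simulated data. Simulated libraries held 2000 planted regions per guide at 90% detection and 300 random summits. Of planted regions detected in 3 of 3 own libraries, at least 88.2% were called. Planted regions missed in any own library were not counted. At least 99.8% of called regions were planted. The rotation test passed 0.05 in 4.5% of 200 random sets. In sets of 1000 random positions, Fisher's test of gene lists passed an unadjusted 0.05 in 11.7% of 700 list tests, more often than its nominal rate.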

Results

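Binding of dCas9 was mapped in 9 libraries of E. coli MG1655, 3 with a control guide against lacZ and 3 each with guides of the AGGAA and ACCCA seeds. The lists held 2844 to 3169 summits for the lacZ guide, 2404 to 2925 for AGGAA and 3075 to 3411 for ACCCA. Chromosomal summits per library averaged 3002 ± 163 (SD, n = 3), 2619 ± 268 and 3234 ± 168 in that order. The number differed between guides in an exact permutation test (p = 0.0393), but this call was lost on leaving out any of 6 single libraries: lacZ replicates 1 and 3, AGGAA replicates 2 and 3, and ACCCA replicates 1 and 2 (exact permutation p from 0.05 to 0.0857). The 3 pairs of guides could not pass on their own, since 3 libraries against 3 cannot give an exact p under 0.1.

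The first comparison asked whether the lacZ guide marked lacZ, the β-galactosidase gene, which checks the labels. In the lacZ libraries the best summit in this gene (363231 to 366305, assembly ASM584v2) lay at 366264 or 366265, 40 or 41 bp inside its upper end. It ranked 4, 3 and 7 in the lists of replicates 1, 2 and 3, a mean of 4.67 ± 2.08 (SD, n = 3). AGGAA libraries had their best lacZ summit at 364769, at a mean rank of 752 ± 22.5 (n = 3). ACCCA libraries had theirs at 365048 or 365049, at a mean rank of 67.3 ± 13.2 (n = 3). Presence alone did not separate the guides, because 9 of 9 libraries had a summit in lacZ (Fisher's exact p = 1). The mean rank was lower with the lacZ guide than in the 6 others (exact permutation over 84 splits, p = 0.0238, two-sided). Peak names inside the lists disagreed with the labels for both of these guides: names in the lacZ lists carried AGGAA, and names in the AGGAA lists carried lacZ. The sample labels were used throughout, so every statement on these guides holds for the libraries labelled so.

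**Figure D1:**
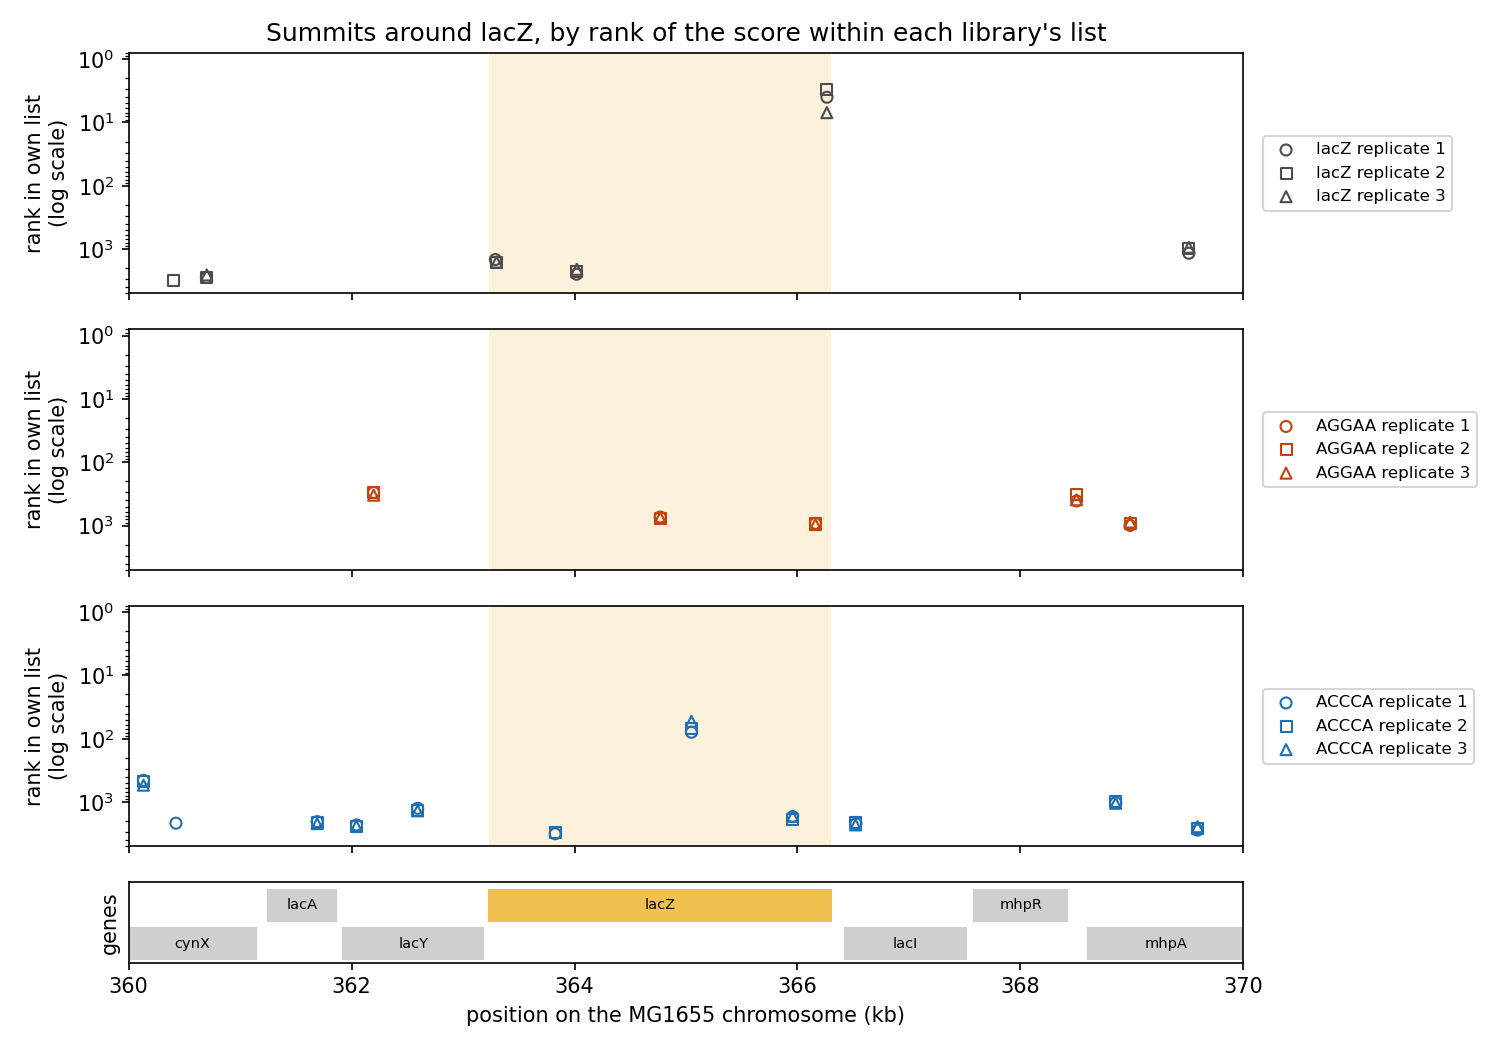
Summits around lacZ in the 9 libraries, with position on the MG1655 chromosome in kb on the horizontal axis and rank of the score in each library's own list on the vertical log axis (rank 1 at the top). Points are single summits, marker shapes are replicates, and the shaded span is lacZ; the lacZ-guide summit near its upper end ranks 3 to 7, and the best AGGAA summit in the gene ranks 733 to 777.

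Libraries of a guide shared most regions, and libraries of different guides few. The Jaccard index averaged 0.831 ± 0.040 (SD, 9 pairs) within guides and 0.0510 ± 0.0034 (27 pairs) between them. The difference of 0.780 passed the exact permutation test (p = 0.00357, one-sided, the smallest it can give). Within guides the index ran from 0.795 to 0.806 for lacZ, 0.778 to 0.862 for AGGAA and 0.848 to 0.902 for ACCCA, and no pair of lists was identical. Of 9092 regions, 2045 were specific to lacZ, 1764 to AGGAA and 2345 to ACCCA, which was 81.1%, 78.2% and 80.3% of the regions found in 3 of 3 libraries of each guide.

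**Figure D2:**
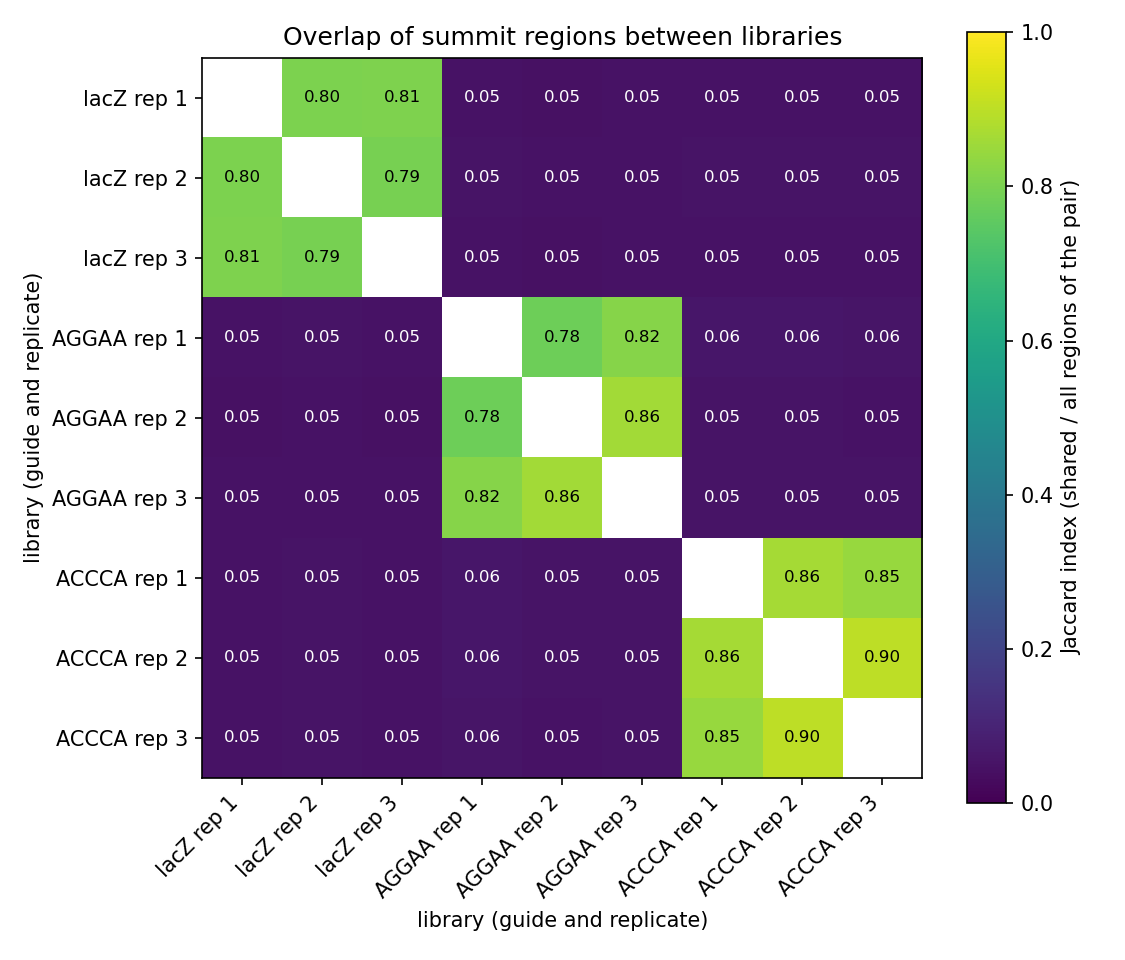
Jaccard index of summit regions for each pair of the 9 libraries, with libraries on both axes and the index (no unit) as colour and number. The 3 blocks along the diagonal hold pairs of the same guide, from 0.778 to 0.902; all other pairs lie between 0.0459 and 0.0591.

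The best-ranked AGGAA-specific regions lay mostly inside genes, as does most of the annotated chromosome (10.7% lies outside genes). Those in pqqL (1574699), aegA (2584198) and glcA (3120680), the glycolate permease gene, ranked 1, 2 and 3 in 3 of 3 libraries. They were followed by gltD, a glutamate synthase subunit (3359985, mean rank 6.67 ± 1.53, n = 3), ulaA, the ascorbate permease (4420605, 7.67 ± 2.08), and uhpB, the sensor kinase for hexose phosphate uptake (3848877, 8 ± 3). Of the 15 named by rank, 14 lay inside genes. The exception, at 4115603, fell between glpX and glpK, the glycerol kinase gene, 24 bp from glpX and 111 bp from glpK (mean rank 10.3 ± 4.04). The others were in iap, nanQ, fieF, prpR, trhA, yhhM, mrcA and rhsA, at mean ranks of 11.7 to 21.

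Among essential genes, the best-ranked AGGAA-specific region lay in pyrG, the CTP synthase gene (2909210, mean rank 40.3 ± 5.03, n = 3). Next came lnt, which acylates lipoproteins (690044, 67.3 ± 17.0), and the division genes ftsI (92407, 78.3 ± 13.6) and ftsA (104403, 101 ± 2.52). A region outside genes lay 36 bp from glyQ, encoding a glycyl-tRNA synthetase subunit, and 59 bp from ysaB (3725354, 92.3 ± 13.3). Another lay 6 bp from yfhR and 139 bp from suhB (2664384, 314 ± 9.02). The remaining named regions were in kdsA, dapE, glmU, wzyE, rpoB, ubiB, ubiD, tyrS and cydC, at mean ranks of 111 to 370. In all, 120 of 290 essential genes held an AGGAA-specific region in the gene or its flanks. The flanks held one for 5.52% of essential genes, close to the 5.39% of other genes. For 16, a region lay in the flanks: hemB, dnaX, rne, prs, ispE, ribA, thrS, der, suhB, rpsP, ffh, cca, infB, rpsJ, glyQ and ssb, listed in full and not by the naming rule.

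ACCCA-specific regions were led by frdA, the fumarate reductase flavoprotein gene (4381188), and gpmM, a phosphoglycerate mutase gene (3786563), at ranks 2 and 3 in 3 of 3 libraries. Further regions lay in aroP, the aromatic amino acid permease gene (121220, mean rank 7 ± 3.61, n = 3), lysC, an aspartate kinase gene (4232686, 13.3 ± 5.77), and mqsA, an antitoxin gene (3168180, 15.7 ± 2.52). yahI and frsA had mean ranks of 17 ± 4.36 and 18 ± 1. The other 8 of the 15 lay in copies of insH, the transposase gene of the insertion sequence IS5, at mean ranks of 5.67 to 17.7. Copies of insH are near-identical, so reads from them may not be assignable to 1 copy, and their values are uncertain.

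Among essential genes, ACCCA-specific regions ranked best in lptB, the ATPase gene of lipopolysaccharide export (3344607, mean rank 37.7 ± 11.0, n = 3), glyS, the other glycyl-tRNA synthetase subunit (3723172, 39.3 ± 6.11), and murE, of peptidoglycan synthesis (93728, 58.7 ± 8.96, and 93202, 133 ± 19.7). A region outside genes lay between eno, the enolase gene, and pyrG (2907999, 62.3 ± 2.52), 30 bp from pyrG and 58 bp from eno. Another lay 10 bp from lexA, the SOS repressor gene, and 100 bp from dgkA (4257105, 121 ± 9.02). A further such region lay 72 bp from ygbE and 122 bp from ftsB, a division gene (2872942, 220 ± 15.3). The remaining named regions were in rpsA, ftsK, folP, glmS, gyrA, asd, rpoB and secA, at mean ranks of 76.3 to 216. ACCCA-specific regions reached 157 of 290 essential genes. The flanks held one for 5.86% of essential genes and 3.46% of other genes (Fisher's exact test, adjusted p = 0.939). For 17, a region lay in the flanks: fldA, rne, zipA, rnc, lepB, ftsB, eno, pyrG, tsaD, rpsU, rpoH, gpsA, rpmH, rnpA, hemC, coaA and lexA, again listed in full.

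The control guide also marked many genes besides lacZ. On the chromosome, yjiG (4559712) ranked 2 in 3 of 3 libraries, and fdhD, needed for formate dehydrogenase activity (4086620), had a mean rank of 4.33 ± 1.53 (n = 3). araA, the arabinose isomerase gene (67893), ranked 5 in 3 of 3 libraries, and metH, a methionine synthase gene (4226536), had a mean rank of 6.33 ± 0.577. hyfE, kdgT, fimF, feoB and rspA followed at 10.7 to 16.7. lacZ-guide regions reached 136 of 290 essential genes, and for 9, a region lay in the flanks: lptD, dxs, ispG, fbaA, pgk, accB, dfp, rplL and rpoB. In the flanks the lacZ-guide share was 3.10% of essential genes, against 3.74% of other genes. Regions of each of the 3 guides were found in or beside 48 of 290 essential genes, and 532 of all 4651 genes.

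By Fisher's exact test, essential genes held regions more often than other genes with each guide. No guide kept this call in the test that rotated its regions around the chromosome. Fisher's test counted genes with a region in the gene or its flanks, whereas the rotation test counted regions inside genes, without flanks. Gene length did not enter Fisher's test. The shares were 41.4% against 33.7% for AGGAA (odds ratio 1.39, adjusted p = 0.0381, Fisher's exact test), 54.1% against 41.2% for ACCCA (1.68, adjusted p = 0.000436) and 46.9% against 36.4% for lacZ (1.54, adjusted p = 0.00326). Permutation by rotation gave 186 ACCCA regions against 156 ± 10.4 rotated (adjusted p = 0.101), 163 against 136 ± 10.1 for lacZ (0.101) and 131 against 117 ± 9.70 for AGGAA (0.409). On simulated sets of 1000 positions Fisher's test passed an unadjusted 0.05 in 11.7% of random list tests, so the calls on other lists carry the same limit. The observed sets were larger, at 1764 to 2345 regions, and their calls were adjusted. The simulated rate therefore does not measure how far those calls are affected. By Fisher's exact test, aminoacyl-tRNA synthetase genes were also higher for lacZ (19 of 23, adjusted p = 0.000406) and ACCCA (18 of 23, adjusted p = 0.00326), with 12 of 23 for AGGAA (adjusted p = 0.195). Division and murein genes were higher for AGGAA (21 of 38, adjusted exact p = 0.0381), with 22 for ACCCA (0.147) and 20 for lacZ (0.174). DNA replication (18 of 25, adjusted exact p = 0.00326) and heat shock genes (15 of 18, adjusted p = 0.00106) were higher for lacZ. AGGAA and ACCCA had 13 and 14 of 25 DNA replication genes (adjusted exact p = 0.203 and 0.308) and 9 and 11 of 18 heat shock genes (0.382 and 0.298). Ribosomal protein genes, which are short, were lower for lacZ (8 of 54, adjusted exact p = 0.00326) and ACCCA (13 of 54, adjusted p = 0.0381), with 11 of 54 for AGGAA (0.100). Differences between guides were not tested. Rotating the regions left 0 of 14 lists past the adjusted threshold for any guide, with 3, 1 and 1 at an unadjusted p under 0.05 for lacZ, AGGAA and ACCCA. Ribosomal protein genes then held 5 lacZ regions against 9.51 ± 2.78 rotated, and 12 ACCCA regions against 10.9 ± 2.92 (permutation by rotation, adjusted p = 0.409 and 0.935). The ACCCA count lay within the SD of the rotated mean, so the lower ACCCA share was not seen there. Synthetase genes held 23 lacZ regions against 17.7 ± 3.57 rotated, and 26 ACCCA regions against 20.3 ± 3.65 (permutation by rotation, adjusted p = 0.409 for each). These and the other lists that had passed kept their direction, at 1.12 to 1.56 times the rotated mean. Regions lay outside genes less often than rotated ones, which by itself raises this ratio for gene lists in general.

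The remaining lists passed neither test for any guide. Members hit by lacZ, AGGAA and ACCCA were 13, 10 and 15 of 28 SOS genes, 13, 15 and 16 of 38 envelope genes, and 13, 3 and 14 of 24 fatty acid and phospholipid genes. They were 17, 14 and 19 of 52 flagellar and chemotaxis genes, 9, 13 and 16 of 35 respiratory genes, and 6, 7 and 6 of 17 transcription genes. For rRNA genes, whose reads may be shared between copies, they were 7, 12 and 11 of 22. In the lac genes (lacI, lacZ, lacY and lacA) they were 1, 2 and 4 of 4.

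The series title concerns promoters, and the nearest measure here was the share of regions outside genes, added after seeing the data. AGGAA libraries had the highest share of summits outside genes, 7.13% ± 0.32 (SD, n = 3), against 4.85% ± 0.34 for lacZ and 4.25% ± 0.03 for ACCCA. The shares differed between guides (exact permutation p = 0.00357), and each pair of guides over full lists reached the smallest p that 3 libraries against 3 allow, 0.1 in an exact test. In equal lists of the best 500 summits the guides lay further apart, at 9.2% to 9.6% for AGGAA, 6% to 7% for lacZ and 3.2% for ACCCA (exact permutation p = 0.00357). With the best 1000 they were at 8.2% to 8.7%, 5.8% to 6.4% and 2.9% to 3% (exact permutation p = 0.00357). Outside genes lay 10.7% of the annotated chromosome. Guide-specific regions fell below it for each guide: 95 of 2045 for lacZ (4.65%), 136 of 1764 for AGGAA (7.71%) and 91 of 2345 for ACCCA (3.88%), each at a permutation p of 0.0001 by rotation, the smallest possible. With the best 500 summits, the AGGAA share was 9.74%, and its difference from the chromosome no longer passed (permutation by rotation, p = 0.499). These comparisons were with the bases of the chromosome, not with sites a guide could bind, since no sequence was used. Whether such sites are fewer outside genes, or differ in this between guides, was not tested. Without strand, promoters could not be told from gene ends.

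**Figure D3:**
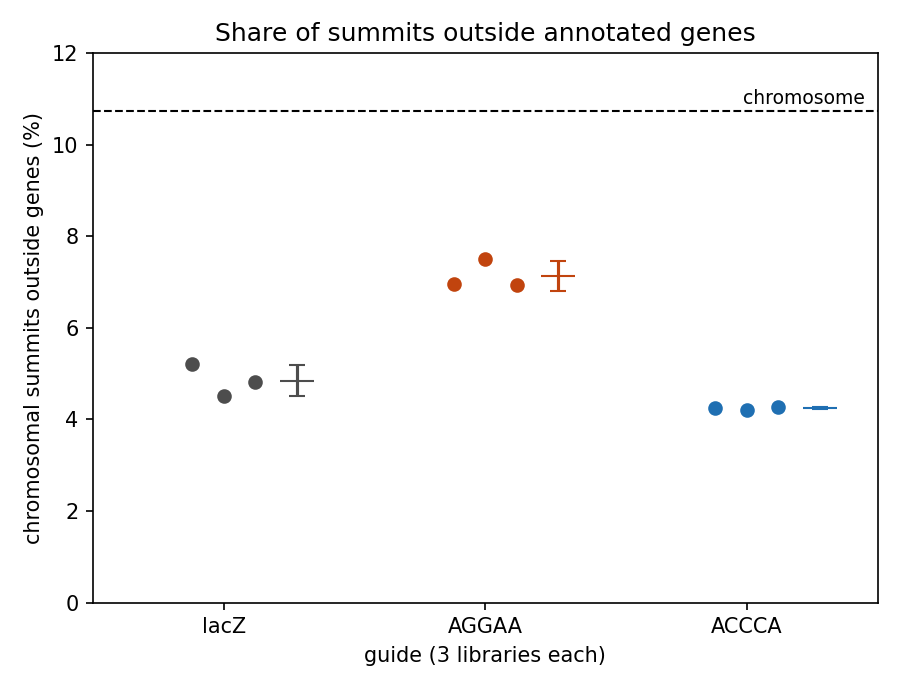
Share of chromosomal summits outside annotated genes, in percent, for each guide. Points are the 3 libraries, the bar beside them is the mean ± SD, and the dashed line is the share of the annotated chromosome outside genes (10.7%); all 9 libraries lie under it and AGGAA libraries are highest, at 6.92% to 7.50%.

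Only 31 regions were found in all 9 libraries, 3 of them outside genes (9.68%, permutation p = 1 by rotation). The best-ranked lay in dsbD, of disulfide exchange (4364684), at ranks from 10 to 796. Others were in ssuD (995946), ybdK (606795), fliA, the flagellar sigma factor gene (2001563), cusB (597944), rmuC (4017937), garL (3273183), glpB (2355327) and fdhF (4298456), and between glnP and glnH, 11 bp from glnP (847130). Their number rested on the distance allowed, with 11 at 25 bp and 101 at 100 bp. In regions shared by libraries of different guides, summits lay a median of 25 to 30 bp apart, against 0 to 1 bp within guides. The dsbD region ran from 4364635 to 4364733, so such regions can join separate summits of different guides. Whether they are common sites was not tested. 0 of 14 gene lists passed for them in Fisher's exact test. The transcription list, with fliA and nusA, named after their values were seen, came closest at 2 of 17 (unadjusted exact p = 0.00621, the lone list under 0.05; adjusted p = 0.0870).

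Guides shared more regions than rotation gave. lacZ and AGGAA shared 158 against 123 ± 10.6 (SD over 1000 rotations, permutation p = 0.002), lacZ and ACCCA 215 against 160 ± 12.3 (p = 0.001), and AGGAA and ACCCA 220 against 143 ± 11.4 (p = 0.001, the smallest possible). Without rRNA, tRNA and insertion sequence genes the counts were 148 against 118 (permutation p = 0.004), 210 against 154 (p = 0.001) and 210 against 137 (p = 0.001). Shared here meant at most 50 bp apart, and whether the pairs are common sites was not tested. Rotation did not keep traits common to the guides, such as the lower share outside genes, so the excess cannot be told from these.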

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

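The comparison of shares outside genes and the look at plasmid summits were chosen only after the data were seen. The count of splits was planned, but how to read it was written after the counts were seen. The share of summits outside genes drew attention because it differed between guides: 7.13% ± 0.32 (SD, n = 3) for AGGAA, 4.85% ± 0.34 for lacZ and 4.25% ± 0.03 for ACCCA (exact permutation p = 0.00357). Summits on plasmid pLC133, which carries dCas9 and entered no comparison, were most numerous in AGGAA libraries, at a mean of 5.33 ± 1.53 (n = 3) against 2.67 ± 0.58 in the control-guide libraries and 3.67 ± 0.58 for ACCCA. The best pLC133 summit lay at 5188 in 3 of 3 AGGAA libraries, at ranks 5 to 18. It lay within 50 bp of that place in lacZ libraries too (5200 to 5203, ranks 78 to 107), and at 5091, 5127 and 6306 in ACCCA libraries (ranks 55 to 77). The difference between guides on this plasmid was not tested.

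Guide-specific regions were counted again in all 84 splits of the 9 libraries into 3 and 6. The ACCCA count of 2345 was reached by 1 split, its own (highest other 2045). The lacZ count of 2045 was reached by 2 splits and the AGGAA count of 1764 by 3 (highest other 2345 for both), and the other splits that reached them were those of the other guides. Splits that mixed guides gave at most 4 regions, so the regions went with the guide. Given the overlaps of the concordance test, this outcome had to follow, so it is no separate evidence and excludes nothing further. Repeats of the same culture would give this outcome too, so it says nothing on how the replicates were made.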

How the results depend on the processing

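Chosen after seeing the data were the alternatives for shares outside genes, for the number and share of regions in all 9 libraries, for rotated gene lists and without repeated genes, and, for summits in lacZ, the best 500 summits and each library left out. The others were planned, with 2 changes. Flanks at both gene ends stood in place of upstream regions. For AGGAA and ACCCA, gene lists were compared with all other genes, not with genes holding a seed and PAM site. Of 163 alternatives, 140 kept the direction and side of the threshold, or the value within its tolerance. Some of these could not change. A replicate block does not enter the counts of guide-specific regions. Every library had a summit in lacZ, so leaving out single libraries could not alter its presence. Guide-specific regions fell with shorter lists by construction, to 440 (lacZ), 462 (AGGAA) and 433 (ACCCA) with the best 500 summits and to 841, 880 and 858 with the best 1000. With the best 500, the AGGAA share outside genes was 9.74% and its call was lost; the cause was not tested. The share outside genes of regions in all 9 libraries, 9.68% against 10.7% of the chromosome, was 18.2% at 25 bp, where 11 regions were left, 4.95% at 100 bp (101 regions), 7.14% with scores of at least 10 and 0% with the best 1000 summits, and ran from 8.82% to 11.8% when single libraries were left out, highest without ACCCA replicate 1; it passed no test, and the cause was not tested. The largest difference in mean summits between guides, 615, ran from 505 to 764 when single libraries were left out and lost its call in 6 of 9 cases, where fewer samples were tested. Concordance ran from 0.765 to 0.790 and kept its call. Lists past the threshold, 5 for lacZ, 2 for AGGAA and 3 for ACCCA, fell to 0 for each guide in flanks alone. They stayed at 5, 2 and 3 with the gene body alone in Fisher's test. They fell to 0 under rotation, which counted regions inside genes in place of genes hit. Same-numbered libraries of different guides correlated from −0.061 to 0.070 in deviations over bins of 10000 bp, so summit positions did not pair by number. Median scores, however, rose with the replicate number in each guide. From replicate 1 to 3 they went from 132 to 344 for lacZ, 263 to 436 for AGGAA and 358 to 920 for ACCCA. A batch or depth that follows the number therefore stays open. With the replicate number as a block, p was 0.0278 for summits per library and for concordance, and mixed splits with 1 library of each number gave at most 2 guide-specific regions against 2045, 1764 and 2345; no call changed. Not run, for want of a sequence and strand here, were the settings foreseen for seed and PAM shares, occupied sites, bases beyond the seed, ranked 5-mers and upstream regions. Read depth is not given in the sources used here, so its effect on the lists is open.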

Other observations

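All tests in this part were chosen after the result was seen. Some families of repeated genes carried summits at the same place in every copy, and others did not. The lacZ guide had them 138 bp from the nearer end in 7 of 7 rrs genes, which encode 16S rRNA, and 232 bp from it in 6 of 6 insD genes, transposase genes of another insertion sequence. AGGAA had them 447 bp from the nearer end in 7 of 7 rrs genes (ranks 159 to 316) and 267 bp from it in 3 of 3 insI genes (ranks 179 to 259). ACCCA had them 562 bp from the nearer end in 3 of 3 insI genes. In 3 of 3 insL genes they lay 417 bp from it for lacZ and 389 bp from it for AGGAA. In some other cases fewer copies had a summit at a common place in 3 of 3 libraries. These included 2 of 7 rrs and 0 of 5 insF genes for ACCCA. AGGAA had 3 of 6 insD genes, and lacZ 4 of 5 insF genes. Of the best 100 guide-specific regions, 12 lay in repeated genes for ACCCA, 0 for lacZ and 0 for AGGAA.

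The guide plasmid psgRNAcos had 1 summit in each of the 9 libraries. It lay at 1850 in lacZ libraries, at 1803 in AGGAA libraries and at 1505 in ACCCA libraries, and ranked 1, 4 and 1 in 3 of 3 lists of each. The longest chromosomal stretch without a region was 8395 bp, from wbbL to rfbD, genes of O-antigen and sugar nucleotide synthesis. Uniform random placement of 9092 regions gave a longest stretch with a median of 4823 bp, and 1 of 1000 draws reached 8395 bp. The next 4 stretches were 6514 bp (yqeK to insD4), 5994 bp (pinR to ydbK), 5323 bp (aaaD to envY) and 5052 bp (ydhV to pykF). Of 1000 draws, 2, 0, 0 and 0 had a stretch as long at the same place in order. Summits were more numerous on the side around the replication origin, at 1.29 (lacZ), 1.40 (AGGAA) and 1.20 (ACCCA) times the other side (means, n = 3 each). The uniform draws did not include this, so their counts test even placement only. Whether the stretches are longer than the observed spread gives was not tested.

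Peak names inside the lists of the lacZ and AGGAA libraries carried the other guide's name. A mislabelled pair of guides would put the strong lacZ summit in the libraries labelled AGGAA. There the best lacZ summit had a mean rank of 752 ± 22.5 (SD, n = 3), against 4.67 ± 2.08 in the libraries labelled lacZ, which argues against swapped labels. Full guide sequences were not used here, so the site itself was not matched, and how the names arose stays open.

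Summits in the transposase gene insH of IS5 were among the highest of the ACCCA lists. A candidate explanation is that reads were shared between near-identical copies. As this requires, 12 of 12 copies had a summit 137 to 138 bp from the nearer end in 3 of 3 libraries, with scores (on the −log10 scale) within 1.41-fold of each other in a library and ranks of 4 to 47. No insH copy held a summit in lacZ libraries, and none held one at a common place in 3 of 3 AGGAA libraries. Binding to a site of the ACCCA guide in every copy and binding to a few copies with reads spread over the rest both stay open, as untested.

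Summits were more numerous on the side of the chromosome centred on the replication origin (midpoint of mnmG and mioC, 3925822) in 9 of 9 libraries, with a ratio to the other side of 1.30 ± 0.10 (SD, n = 9) and a gene density ratio of 0.988. Libraries of a guide shared most regions, so these 9 are not independent. For guide-specific regions, the share on that side was 55.0% for lacZ (permutation p by rotation = 0.0226), 55.8% for AGGAA (p = 0.137) and 53.3% for ACCCA (p = 0.175), 3 tests without adjustment. If weak summits passed the threshold more often near the origin, the lowest-scored of 3 equal parts of each list was predicted to show the higher ratio. In AGGAA libraries weak summits may account for part, at 1.88 ± 0.030 in the lowest against 1.27 ± 0.031 in the highest part (n = 3). ACCCA went against the prediction, at 1.04 ± 0.018 against 1.66 ± 0.073. In lacZ libraries the parts cannot be told apart (1.34 ± 0.064 against 1.29 ± 0.114), since they differ by less than the SD. The parts cannot exclude the explanation for any guide, because the lowest part was not limited to summits near the threshold. For ACCCA replicate 1 it held a score of 201 (rank 2300 of 3411), against a lowest score of 4.14. A higher DNA copy number near the origin of growing cells stays open, as no input library was used here, and no biological explanation was tested.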
